A study of Mus musculus with 10 samples.

How the data were processed

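RNA of primary hepatocytes from mice was measured on Affymetrix Mouse Gene arrays, a platform named in the probe annotation, in 10 libraries that each pooled RNA of 3 culture dishes. Per the labels, cells were transduced for 72 hours with an adenovirus (2 to 4 plaque-forming units per cell) carrying a non-specific short hairpin RNA (shNS), one against Wdr5 (shWDR5) or one against Kat2b (shKAT2B), and then treated for 90 minutes with 100 nM glucagon or with phosphate-buffered saline (PBS). The deposited table gives intensity on a linear scale, from 4.47 to 22694, for 26913 features, and the log2 of every deposited value has 2 decimals. Affymetrix Expression Console 1.1.1 is named per the submitters' processing notes, and the normalization method is not given in the sources used here. Library medians lay between 282.1 and 298.2. The lowest of the features' highest values over the 10 libraries was 52.7, and whether the table was filtered is not given in the sources used here. An array has no read depth, so the number of libraries limits the precision.

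Of the features, 17873 carried 1 gene symbol, 1128 carried several and 7912 had no gene in the annotation. Of those with 1 symbol, 17815 were matched by gene identifier to a RefSeq gene table and 0 symbols needed updating. Features with 1 symbol covered 16401 genes, of which 847 had more than 1 feature, and the feature with the highest mean was kept for each gene. Values were taken as log2(intensity + 1), and the lowest 30 percent of genes by mean over all libraries were left out, which left 11480 genes tested. The genome build behind the annotation is not given, so no positions are printed.

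Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean expression), and tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. An additive model of arm and treatment gave the glucagon effect shared by the arms and the knockdown effects over both treatments, with 6 residual degrees of freedom. A model of the 6 groups gave the glucagon effect in each arm, the knockdown effects under glucagon and the interactions, with 4 residual degrees of freedom. In both, groups with 1 library (shWDR5 PBS and shKAT2B PBS) were assumed to vary like the other groups. Tests were two-sided, adjusted p are Benjamini-Hochberg values over the genes tested, and a gene was called at an adjusted p below 0.05. Errors given after ± are the model's standard errors unless another is named. Because each library is a pool and nothing in the labels says that the letters A and B are separate animals, the p-values measure the spread between these libraries.

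Of 30 gene lists, 28 had enough tested members and were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Counts of called list members in the fits without a batch term are also given adjusted over the list alone. Of 308 list tests 85 passed, and 9 of these also passed with a correlation estimated from the residuals. In none of the 85 did the list's median and mean differ in sign (0 tests). Genes called higher with a log2 fold change of at least 1 in the shared glucagon effect, and genes called lower by at least as much, were tested as 2 sets for their interaction with each knockdown, using limma's fry, which asks whether a set moves on balance one way.

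The genes named are the targets Kat2b and Wdr5, 6 known glucagon-responsive genes (Nr4a1, Ppargc1a, Crem, G6pc, Pck1 and Tat), up to 10 called genes with the highest and up to 10 with the lowest log2 fold change per comparison, and up to 4 members of each list that passed. Those named by size were required not to overlap between the groups compared within each arm or each treatment. Where fewer than 5 genes were called in a direction, those with the smallest p in that direction could be named and are said not to pass. The lists, the naming rule, the models, the thresholds and the other settings to be tried were set before the data were examined. These other settings were quantile normalization, median-centred libraries, other filters, the mean of a gene's features, no trend, a pseudocount of 16, the replicate letter as a block, fewer libraries and leaving out each library in turn. Without its lone PBS library a depletion arm holds only glucagon libraries, so its values then rest on glucagon-treated cells.

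Residuals of the additive model split the libraries into 2 sets, called library batches here, by the sign of their first component. Fits with this batch as a term, fits on the second batch alone and fits without a pseudocount were added after seeing the data. The second batch holds 1 library of each group, so in fits on it alone no group is replicated. Their spread comes only from departures from the additive model, so their counts cannot be set against those of all 10 libraries. The batch was read from the same libraries, so fits that contain it are alternatives and do not replace the fits chosen first. The models were checked on simulated data made with the design's group sizes. Noise was drawn independently for each gene, with the spread left after the batch term, and fits with the term were given the simulated batch. They therefore do not check a batch read from the same data. Unchanged genes called numbered 1 for the shared glucagon effect and 0 for the WDR5 interaction, and 11 and 10 with the batch term. For the shared glucagon effect, genes changed by 0.5, 1 and 2 on the log2 scale were called in 62.7, 91 and 100 percent of cases. For an interaction with WDR5 knockdown, the same sizes were called in 0, 20.9 and 74.2 percent of cases, and in 25.4, 92.5 and 100 percent with the batch term.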

Results

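Gene expression was measured in primary mouse hepatocytes after depletion of WDR5, a core subunit of histone methyltransferase complexes, or KAT2B, a histone acetyltransferase, with and without glucagon, the fasting hormone that raises cyclic AMP in hepatocytes. The 10 libraries formed 6 groups, with 2 libraries (A and B) in shNS PBS, shNS glucagon, shWDR5 glucagon and shKAT2B glucagon and 1 library in shWDR5 PBS and in shKAT2B PBS. Median intensity ranged from 282.1 to 298.2 over the libraries. The comparisons address how each depletion changed hepatocyte gene expression, as the series title states.

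Libraries also differed in a way that arm and treatment did not account for. The leading component of what the additive model left over held 78 percent of the residual variance and separated 4 libraries (shNS PBS A, shNS glucagon A, shWDR5 glucagon A and shKAT2B glucagon A) from the other 6, which hold 1 library of each group. Markers of Kupffer cells and leukocytes, cells of the liver other than hepatocytes, were higher in this second batch by a median of 0.52 on the log2 scale, with 15 of 15 measured members called. Endothelial markers were higher by 0.51, and stellate cell and fibroblast markers were lower, at -0.37. Cholesterol synthesis genes stood at 0.52 and cell cycle genes at 0.61 between the batches. None of these lists passed with an estimated correlation (adjusted p = 0.206 for each). The lone PBS libraries of the knockdown arms carry the letter A but lay with the B libraries, as judged by their correlation across genes with the glucagon libraries of their own arm once the glucagon effect seen in shNS was added. For shWDR5 it was 0.9956 with glucagon B and 0.9824 with glucagon A, and for shKAT2B 0.9958 and 0.9757 (genes are not independent replicates). Values with the batch as a term of the fit, or within the second batch, are therefore given beside the others.

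**Figure D1:**
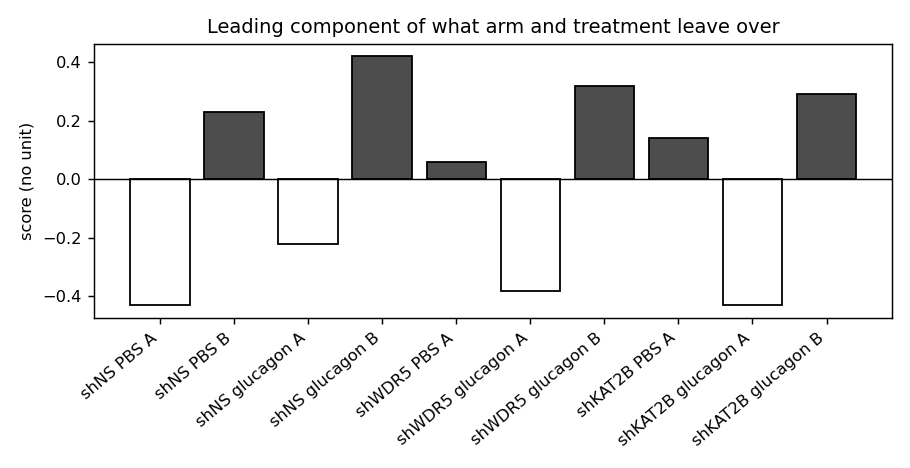
Score of each library on the leading component of the residuals of arm and treatment (bars, no unit; white for the first library batch, dark for the second). The 4 libraries of the first batch lie between -0.43 and -0.22 and the other 6 between 0.06 and 0.42.

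Each hairpin lowered its target in every library of its arm. Kat2b (feature 10445909) stood at 6.61 in shKAT2B PBS and at 6.93 and 6.60 in shKAT2B glucagon, against 9.40 to 9.59 in the 7 libraries of the other arms (log2 intensity). That was a change of -2.70 ± 0.09, or 6.52-fold lower (3 against 4 libraries, adjusted p = 2.75e-06). Wdr5 (feature 10470427) stood at 8.19 in shWDR5 PBS and at 8.32 and 8.40 in shWDR5 glucagon, against 9.98 to 10.07 elsewhere, a change of -1.74 ± 0.07 or 3.33-fold lower (3 against 4 libraries, adjusted p = 1.33e-05). Kat2b differed from shNS by 0.10 ± 0.09 in the WDR5 arm (adjusted p = 0.543) and Wdr5 by 0.00 ± 0.07 in the KAT2B arm (adjusted p = 0.991). The labels list no other hairpin against either target, and protein was not measured here. Effects of a depletion therefore cannot be told apart from other effects of its hairpin, and depletion here names the arm.

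**Figure D2:**
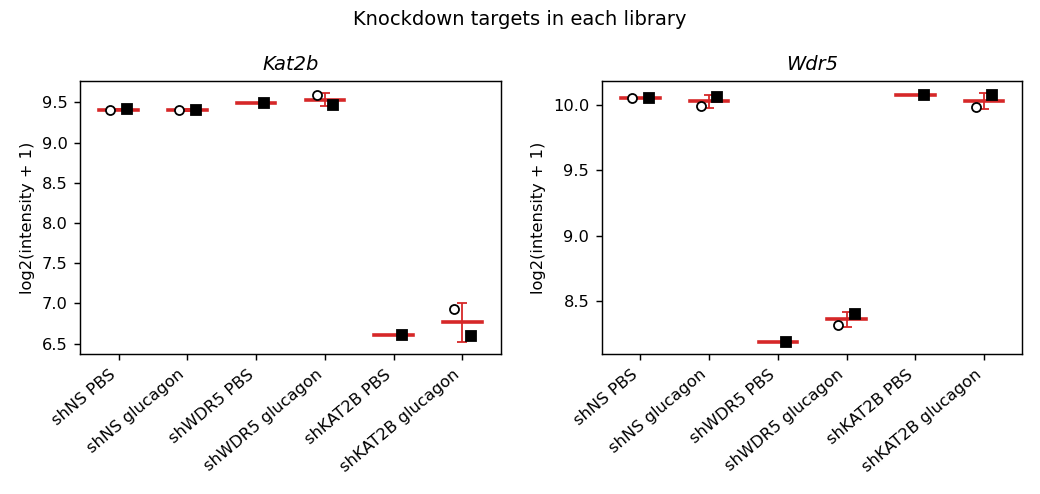
Kat2b and Wdr5 in each library (y axis, log2 of intensity + 1; circles for the first library batch, squares for the second; red bars for the group mean and, where a group has 2 libraries, its SD). Each target lies lower in the 3 libraries of its own arm than in the other 7.

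Glucagon raised the orphan nuclear receptors Nr4a1, Nr4a3 and Nr4a2, immediate targets of cyclic AMP signalling, by 3.28 ± 0.15, 2.77 ± 0.14 and 2.47 ± 0.20 on the log2 scale over the 3 arms (6 glucagon against 4 PBS libraries). G6pc, the catalytic subunit of glucose-6-phosphatase that releases glucose from the liver, rose by 3.16 ± 0.33, and Tat, which starts tyrosine breakdown, by 2.92 ± 0.22. Ppargc1a, a coactivator of fasting genes, rose by 1.70 ± 0.07, the kinase gene Sik1 by 1.99 ± 0.08, the cationic amino acid transporter gene Slc7a2 by 1.73 ± 0.11 and Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factors, by 2.11 ± 0.14. Rgs2 and Rasgef1b, regulators of G proteins, rose by 1.86 ± 0.18 and 1.97 ± 0.14. Edn1 (endothelin), F3 (tissue factor) and the immediate early gene Egr1 fell, at -1.21 ± 0.14, -1.11 ± 0.14 and -0.84 ± 0.07. Adjusted p were 1.72e-05 for Nr4a1, 0.00203 for G6pc, 0.000307 for Tat, 1.11e-05 for Ppargc1a, 0.00466 for Edn1 and 0.000393 for Egr1 (limma, Benjamini-Hochberg). Within each arm no glucagon library overlapped a PBS library for these genes, which held for all 106 called genes. Called genes were picked on these same libraries, here and for the depletions below, so a lack of overlap is not separate support. Pck1, the gluconeogenic enzyme PEPCK, rose by 1.64 ± 0.30 (adjusted p = 0.0396) and the cyclic AMP-responsive factor gene Crem by 0.65 ± 0.10 (adjusted p = 0.0149). Pck1 did not pass without any 1 of 8 libraries, up to an adjusted p of 0.174 without shWDR5 PBS A, and Crem did not pass without shNS glucagon B, shWDR5 PBS A or shKAT2B PBS A (adjusted p = 0.0522, 0.125 and 0.0738). Both also missed the threshold in median-centred libraries (adjusted p = 0.0771 for Pck1 and 0.0607 for Crem).

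For the shared glucagon effect 549 genes had an unadjusted p under 0.05 (limma), where 574 would be expected by chance. With the batch as a term 1213 genes had one, so the 549 alone do not show that few genes responded. Over all genes, 106 were called for this effect, 78 higher and 28 lower. The count was 385 with the batch term (221 higher, 164 lower) and 309 within the second batch, and all 106 genes were among the 385. Without shNS PBS B, shNS glucagon A, shWDR5 PBS A or shKAT2B PBS A the count was 61, 60, 50 and 54.

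**Figure D3:**
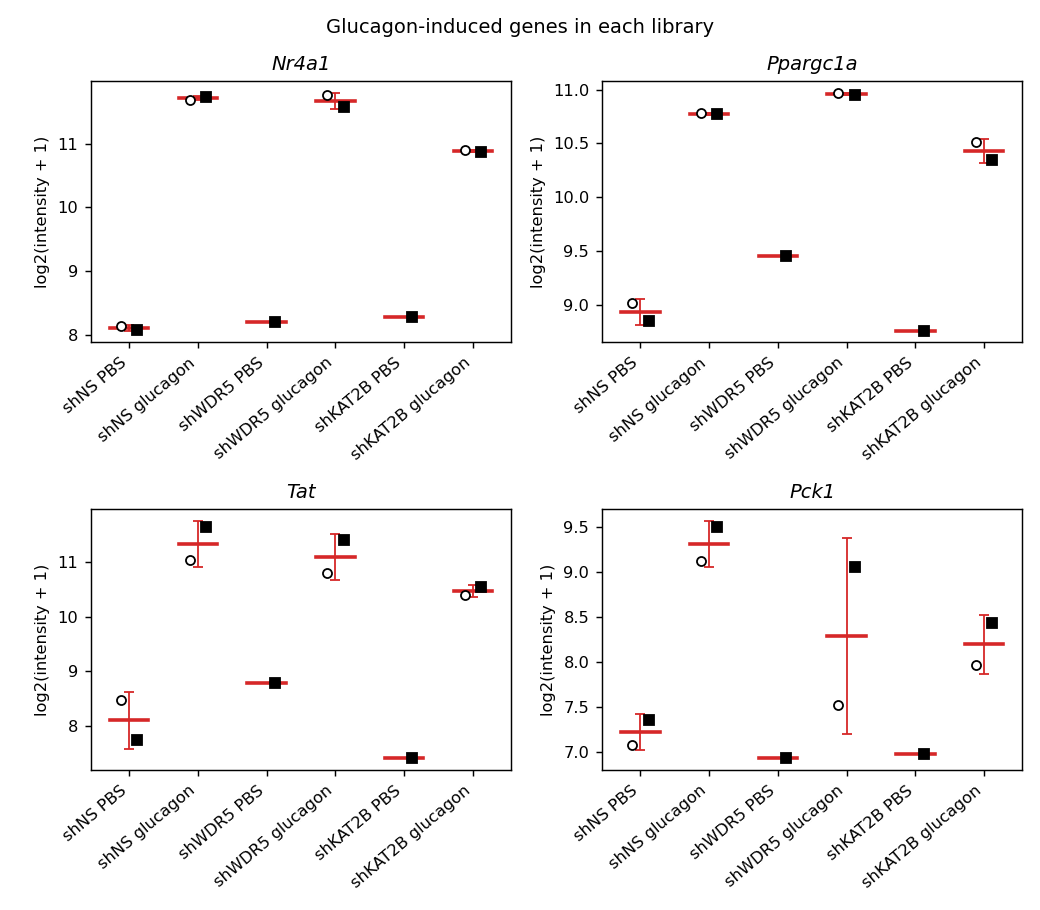
Nr4a1, Ppargc1a, Tat and Pck1 in each library (y axis, log2 of intensity + 1; circles for the first library batch, squares for the second; red bars for the group mean and, where a group has 2 libraries, its SD). Every glucagon library lies above the PBS libraries of its arm.

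Among CREB and cAMP immediate targets, 10 of 22 measured members rose and 2 fell (16 and 4 adjusted over the list alone), with a median of 0.71 (camera, adjusted p = 3.52e-21), and the call held with an estimated correlation (adjusted p = 0.0129). Within the second batch the list's median was 0.88 in shNS, 0.50 in shWDR5 and 0.44 in shKAT2B. Of 14 gluconeogenesis genes 5 rose and 0 fell (6 and 0 adjusted over the list alone), among them G6pc, Pck1, Ppargc1a and Sik1. Their median was 0.19 (adjusted p = 8.2e-09, and adjusted p = 0.0823 with an estimated correlation). Of 11 genes of amino acid catabolism and the urea cycle 3 rose (4 adjusted over the list alone), namely Tat, Slc7a2 and the transporter gene Slc38a4 at 0.27 ± 0.05, and the other 8 were not called. This list passed with an estimated correlation as well (median 0.11, adjusted p = 6.79e-08 and 0.0129). For all 3 lists the adjusted p with an estimated correlation was 0.0593 once the batch was a term. The call of Slc38a4 ended without any 1 of 9 libraries, up to an adjusted p of 0.199 without shWDR5 PBS A, and in median-centred libraries (adjusted p = 0.057).

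Lower medians under glucagon were found for cholesterol synthesis and SREBP2 targets (-0.14, 0 of 15 members called, 0 adjusted over the list alone, adjusted p = 0.00239) and for cell cycle and DNA replication (-0.19, 0 of 19 called, 0 adjusted over the list alone, adjusted p = 0.02). Kupffer cell and leukocyte markers moved with them, at -0.14 (0 of 15 called, 0 adjusted over the list alone, adjusted p = 0.0449). The adjusted p with an estimated correlation was 0.787 for all 3 lists. Fitted with the batch, their medians were -0.01, 0.01 and 0.05 (adjusted p = 0.669, 0.724 and 0.189), and within the second batch the Kupffer list turned to 0.10 (adjusted p = 0.000925). The cholesterol and cell cycle calls also ended without shNS PBS B, shNS glucagon A, shWDR5 glucagon A, shKAT2B PBS A or shKAT2B glucagon A, with medians as small as -0.07 and -0.03 and adjusted p of up to 0.17 and 0.555. The Kupffer call ended without any of these 5 or shWDR5 PBS A (median -0.03 and adjusted p = 0.642 without shKAT2B glucagon A). Acute phase and NF-kB genes had a median of -0.15 (adjusted p = 0.0031, and adjusted p = 0.558 with an estimated correlation), with 1 of 16 members lower and 0 higher (2 and 1 adjusted over the list alone), and 0.01 with the batch term (adjusted p = 0.36), and it missed without shNS PBS B (adjusted p = 0.0569). The member that fell was the chemokine gene Cxcl1, at -0.87 ± 0.16 (adjusted p = 0.0489), whose call ended without any 1 of 9 libraries, up to an adjusted p of 0.282 without shKAT2B PBS A. Hepatocyte identity genes had a median of 0.02 (adjusted p = 0.02, and adjusted p = 0.668 with an estimated correlation), and the 1 of 18 members called was Tat (3 higher adjusted over the list alone). This call ended without shNS PBS A, shNS glucagon B or shWDR5 glucagon B (adjusted p = 0.508, 0.208 and 0.12).

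WDR5 depletion lowered Vkorc1, the vitamin K epoxide reductase (-1.30 ± 0.08 on the log2 scale), the growth factor gene Hdgf (-1.10 ± 0.06), the nuclease gene Endod1 (-1.30 ± 0.12) and Aph1a, a subunit of gamma-secretase (-1.09 ± 0.13; 3 shWDR5 against 4 shNS libraries). It raised the interleukin gene Il1f9 by 2.36 ± 0.24, the lipoprotein receptor gene Olr1 by 1.22 ± 0.20 and Ripply1 by 1.32 ± 0.10. Adjusted p were 0.000128 for both Vkorc1 and Hdgf, 0.000729 for Endod1, 0.00287 for Aph1a, 0.00154 for Il1f9, 0.0076 for Olr1 and 0.00068 for Ripply1. No shWDR5 library overlapped an shNS library of the same treatment for these genes, as the naming rule required and as held for all 1246 called genes. Each of these calls held whichever library was left out. Il1f9 differed by 2.16 under glucagon in the first batch, and by 2.32 under glucagon and 2.34 in PBS in the second, and Vkorc1 by -1.19, -1.38 and -1.22. The cell division genes Cep55 and Kif20a, which act late in mitosis, rose by 1.30 ± 0.27 and 1.16 ± 0.24 (adjusted p = 0.0185 and 0.0179). Both calls ended without shNS glucagon A, shWDR5 PBS A or shWDR5 glucagon B, up to an adjusted p of 0.106 and 0.107. Ppargc1a rose by 0.32 ± 0.08 (adjusted p = 0.0444), a call that ended without any 1 of 9 libraries (adjusted p = 0.286 without shWDR5 PBS A) and without the filter on low values (adjusted p = 0.059). Nr4a1 differed by 0.06 ± 0.18, Tat by 0.12 ± 0.26, G6pc by -0.53 ± 0.39, Pck1 by -0.70 ± 0.35 and Crem by -0.33 ± 0.11, and none of these 5 passed (adjusted p = 0.881, 0.833, 0.446, 0.244 and 0.101). For Tat and G6pc these values average opposite signs. Within batches Tat differed by -0.24 and -0.24 under glucagon and by 1.05 in PBS, and G6pc by -1.25, -0.64 and 0.28. Pck1 and Crem were lower in each. Pck1 and Crem passed with the batch term, at -0.86 and -0.37, and on the second batch alone, at -0.43 and -0.36 (adjusted p = 0.0463 and 0.0293). Under glucagon Pck1 differed by -1.61 in the first batch and by -0.44 in the second. Crem also passed without shWDR5 glucagon B (-0.46, adjusted p = 0.0394).

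In all, 1246 genes were called under WDR5 depletion, 538 higher and 708 lower. The batch term raised this to 4227 (2155 higher, 2072 lower), which included all 1246, and 3202 were called within the second batch. The count was 787 without shNS PBS B, 479 without shNS glucagon A, 300 without shWDR5 PBS A, 519 without shWDR5 glucagon B, 804 without shKAT2B PBS A and 813 with only the libraries of the 2 arms.

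Cell cycle and DNA replication genes were higher after WDR5 depletion, with a median of 0.58 over 19 members (camera, adjusted p = 6.15e-06, and adjusted p = 0.873 with an estimated correlation). Of these 3 rose and 0 fell (8 and 0 adjusted over the list alone): the mitotic kinase gene Cdk1 by 0.58 ± 0.10, the proliferation marker Mki67 by 0.74 ± 0.16 and Cdc20, an activator of the anaphase-promoting complex, by 1.15 ± 0.30. In the fit with the batch 14 members rose and the median was 0.55, and the differences within batches were 0.62 and 0.54 under glucagon and 0.41 in PBS. Mki67 did not pass without shNS glucagon A, shWDR5 PBS A or shWDR5 glucagon B (adjusted p of up to 0.115), nor Cdc20 without any 1 of 6 libraries (up to 0.179 without shWDR5 PBS A) or after quantile normalization (0.0548). Kupffer cell and leukocyte markers moved the same way, at a median of 0.27 with 0 of 15 called (0 adjusted over the list alone, adjusted p = 0.0197), as did endothelial markers at 0.30 with 0 of 14 called (0 adjusted over the list alone, adjusted p = 0.0258), each with an adjusted p = 0.873 with an estimated correlation. These markers stood at 0.17 and 0.19 with the batch term, with 7 and 5 members higher. Both marker calls ended without shNS PBS A, shNS glucagon A, shWDR5 PBS A or shWDR5 glucagon B, up to an adjusted p of 0.26 and 0.262, and in median-centred libraries (0.0661 and 0.0908).

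Of 21 ribosome biogenesis genes 7 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.25 (adjusted p = 6.79e-08, and adjusted p = 0.398 with an estimated correlation). Dkc1, which pseudouridylates ribosomal RNA, rose by 0.49 ± 0.10, Rrp1b by 0.37 ± 0.08 and Utp20 by 0.34 ± 0.06, and with the batch term 19 of 21 rose. Without shWDR5 PBS A none of these 3 passed (adjusted p = 0.0712, 0.0845 and 0.0894). Dkc1 and Rrp1b also missed without shNS glucagon A (0.0644 and 0.0508), and Dkc1 without shWDR5 glucagon B (0.0569). Cytosolic ribosomal protein genes moved the other way, with 5 of 21 lower and 0 higher (6 and 0 adjusted over the list alone), Rps3 by -0.38 ± 0.06 and Rps7 by -0.32 ± 0.04. Their median was -0.15 (adjusted p = 0.0088, and adjusted p = 0.873 with an estimated correlation), and -0.20 with the batch term, where 14 of 21 fell. That call ended without shNS glucagon B (adjusted p = 0.15), without shWDR5 glucagon A (0.112) and in median-centred libraries (0.0619).

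Genes of endoplasmic reticulum stress and the amino acid response were higher by a median of 0.13, with 5 of 16 called (5 adjusted over the list alone). Among them were the chaperone genes Dnajb9 at 0.60 ± 0.12 and Hsp90b1 at 0.38 ± 0.08 (list adjusted p = 0.0129, and adjusted p = 0.873 with an estimated correlation). Hepatocyte identity genes were lower by a median of -0.18, with 3 of 18 called (3 adjusted over the list alone): albumin (Alb) at -0.30 ± 0.07, transferrin (Trf) at -0.24 ± 0.04 and the transcription factor gene Prox1 at -0.43 ± 0.11. Fatty acid oxidation and ketogenesis genes also had a median of -0.18, with 3 of 13 lower (3 adjusted over the list alone), namely Ehhadh, Acadvl and Hadhb, at -0.43 ± 0.10, -0.37 ± 0.07 and -0.22 ± 0.05. The list tests gave adjusted p = 0.0197 and 0.0352, and adjusted p = 0.873 with an estimated correlation for both lists. The calls of all 3 lists ended without shWDR5 glucagon A (adjusted p = 0.112, 0.312 and 0.112), and that of hepatocyte identity also without shNS glucagon B (0.135). The fatty acid oxidation call ended as well without shNS PBS A, shNS glucagon A, shNS glucagon B or shWDR5 PBS A (0.0572, 0.0844, 0.072 and 0.0539) and within the second batch (0.0726). Of the genes named here, Trf alone kept its call whichever library was left out, and it missed in median-centred libraries (0.0577).

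**Figure D4:**
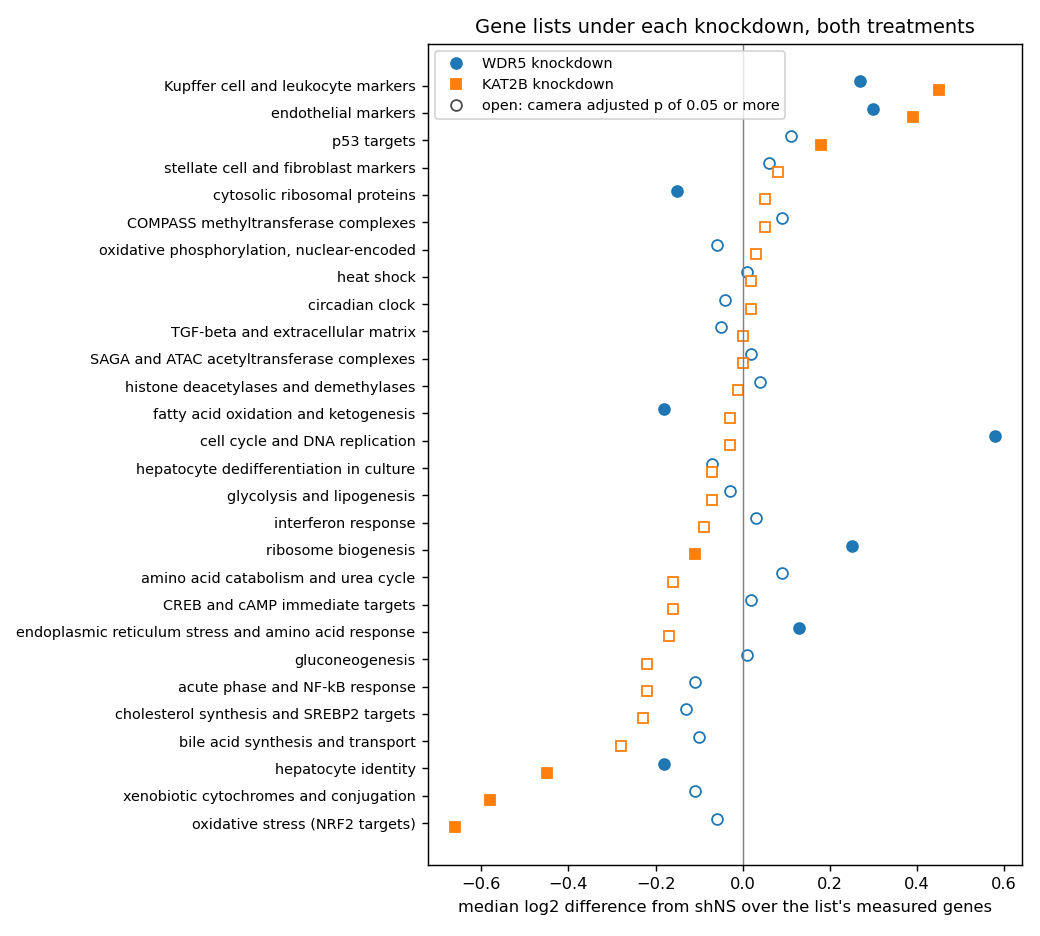
Median log2 difference from shNS (x axis) of the measured members of each of 28 gene lists (y axis) under WDR5 knockdown (blue circles) and KAT2B knockdown (orange squares), over both treatments; filled marks have a camera adjusted p below 0.05. The cell cycle list lies at 0.58 under WDR5 knockdown and the oxidative stress list at -0.66 under KAT2B knockdown.

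KAT2B depletion lowered Hamp, which encodes the iron-regulating hormone hepcidin, 7.41-fold (-2.89 ± 0.38 on the log2 scale, adjusted p = 0.00165; 3 shKAT2B against 4 shNS libraries). Akr1c14, a hydroxysteroid dehydrogenase, changed by -1.78 ± 0.10 (adjusted p = 4.19e-05), Hpgd, which inactivates prostaglandins, by -1.75 ± 0.21 (0.00105), the lysyl oxidase gene Lox by -1.83 ± 0.30 (0.00397) and the adipokine gene Serpina12 by -1.62 ± 0.15 (0.000356). Alox5, the lipoxygenase of leukotriene synthesis, rose by 2.09 ± 0.16 (adjusted p = 0.00016), the semaphorin gene Sema6a by 2.10 ± 0.24 (0.000876), the co-stimulatory ligand gene Cd80 by 1.99 ± 0.17 (0.000259), the chemokine gene Cxcl13 by 1.64 ± 0.23 (0.00194) and the plasma glutathione peroxidase gene Gpx3 by 1.59 ± 0.22 (0.0022). Hamp differed by -2.27 under glucagon in the first batch, and by -3.22 under glucagon and -3.96 in PBS in the second, and Alox5 by 1.88, 2.32 and 2.43. All of these calls held whichever library was left out. No shKAT2B library overlapped an shNS library of the same treatment for these genes, as the naming rule required and as held for 1774 of the 1792 called genes. Among the glucagon-responsive genes, Nr4a1 differed by -0.43 ± 0.18, Ppargc1a by -0.26 ± 0.08, Pck1 by -0.75 ± 0.35, Tat by -0.76 ± 0.26, G6pc by -0.50 ± 0.39 and Crem by -0.02 ± 0.11, and none of these 6 passed (adjusted p = 0.149, 0.0675, 0.194, 0.083, 0.45 and 0.939). Nr4a1, Ppargc1a, Pck1 and Tat passed with the batch term, at -0.44, -0.25, -0.90 and -0.81. On the second batch alone they stood at -0.33, -0.25, -0.72 and -0.71, and Nr4a1 did not pass there (adjusted p = 0.184, 0.0494, 0.00259 and 0.0204). Leaving out 1 library brought a call for Nr4a1 (-0.79 without shKAT2B PBS A), Ppargc1a (-0.32 without shNS PBS B), Pck1 (-0.78 without shWDR5 glucagon A) and Tat (-0.93 without shNS PBS B, -0.78 without shWDR5 glucagon A). Without shKAT2B PBS A the arm holds only glucagon libraries, so this value for Nr4a1 is a difference under glucagon. Within batches Nr4a1 differed by -0.79 and -0.86 under glucagon and by 0.21 in PBS, and G6pc by -0.70, -1.12 and 0.29. Ppargc1a, Pck1 and Tat were lower in each.

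Under KAT2B depletion 1792 genes were called, 764 higher and 1028 lower. All of these were among the 4768 called with the batch term (2465 higher, 2303 lower). Within the second batch 4263 were called. The count was 1107 without shNS glucagon A, 598 without shKAT2B PBS A and 968 without shKAT2B glucagon B.

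Of 12 oxidative stress genes that NRF2 activates, 11 fell and 0 rose under KAT2B depletion (12 and 0 adjusted over the list alone), with a median of -0.66 (camera, adjusted p = 1.73e-10), and the call held with an estimated correlation (adjusted p = 0.0128). Srxn1 (sulfiredoxin) changed by -0.94 ± 0.06, Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, by -0.91 ± 0.11 and the quinone reductase gene Nqo1 by -0.88 ± 0.16. The list's medians within batches were -0.68 and -0.63 under glucagon and -0.63 in PBS, and with the batch term the adjusted p with an estimated correlation was 0.116. Of 7 xenobiotic cytochromes and conjugation genes 3 fell (5 adjusted over the list alone), namely Nr1i2, the pregnane X receptor, at -1.16 ± 0.15, and the glutathione transferase genes Gsta3 at -0.75 ± 0.04 and Gstm1 at -0.58 ± 0.05. That list's median was -0.58 (adjusted p = 0.000275, and adjusted p = 0.0711 with an estimated correlation), and Gstm1 is in both lists.

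Hepatocyte identity genes fell in 9 of 18 cases and rose in 0 (12 and 0 adjusted over the list alone), with a median of -0.45 (adjusted p = 1.26e-07, and adjusted p = 0.0972 with an estimated correlation). Examples are the plasma protein genes Apoa2 at -1.02 ± 0.14, Ttr at -0.91 ± 0.08 and Fga at -0.75 ± 0.14. The batch term brought this to 17 of 18, and the medians within batches were -0.47 and -0.49 under glucagon and -0.45 in PBS. Markers of other liver cells were higher beside them: Kupffer cell and leukocyte markers by a median of 0.45 (0 of 15 called, 0 adjusted over the list alone, 10 with the batch term at 0.30, adjusted p = 0.0303) and endothelial markers by 0.39 (1 of 14 called, 1 adjusted over the list alone, 10 with the batch term at 0.27, adjusted p = 0.0176). With an estimated correlation the adjusted p of these were 0.888 and 0.787. Both marker calls ended without shNS PBS A, shNS glucagon A, shKAT2B PBS A or shKAT2B glucagon B, up to an adjusted p of 0.191 and 0.109, and in median-centred libraries (0.142 and 0.0702). Stellate cell and fibroblast markers stood at 0.08 (adjusted p = 0.905).

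The p53 target list had 4 of 13 members higher and 0 lower (4 and 0 adjusted over the list alone), among them the anti-proliferative gene Btg2 at 0.61 ± 0.07 and the death receptor gene Tnfrsf10b at 0.45 ± 0.07. Its median was 0.18 (adjusted p = 0.0253, and adjusted p = 0.653 with an estimated correlation), and it missed without shNS glucagon B (adjusted p = 0.056). Of 21 ribosome biogenesis genes 5 fell and 0 rose (5 and 0 adjusted over the list alone), including Dkc1 at -0.68 ± 0.10 and Wdr43 at -0.47 ± 0.05. The median there was -0.11 (adjusted p = 0.0025, and adjusted p = 0.565 with an estimated correlation). The acetyltransferase complexes that hold KAT2B had 1 of 21 members called, Kat2b itself (1 adjusted over the list alone), and a median of 0.00 (adjusted p = 0.591). Under WDR5 depletion the methyltransferase complexes that hold WDR5 had a median of 0.09 over 18 members (adjusted p = 0.579), with 1 higher and 1 lower (1 and 1 adjusted over the list alone).

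Set directly against each other, the depletions differed in Il1f9 by -3.09 ± 0.25 for KAT2B minus WDR5 (3 against 3 libraries, adjusted p = 0.000144). Hamp and Tdo2, which starts tryptophan breakdown, were lower under KAT2B depletion, at -2.33 ± 0.41 and -2.08 ± 0.10. Gpx3 was higher by 2.19 ± 0.24, Alox5 by 1.97 ± 0.17 and Vkorc1 by 1.71 ± 0.08. Ribosome biogenesis genes were lower under KAT2B than under WDR5 depletion in 15 of 21 cases and higher in 0 (18 and 0 adjusted over the list alone), with Dkc1 at -1.17 ± 0.10 and Nop56 at -0.59 ± 0.07. Their median was -0.37 (adjusted p = 1.41e-09, and adjusted p = 0.0893 with an estimated correlation). Oxidative stress genes were lower in 10 of 12 cases (12 adjusted over the list alone; median -0.54, adjusted p = 7.22e-08), which held with an estimated correlation (adjusted p = 0.0304). Cell cycle genes were lower in 6 of 19 cases (9 adjusted over the list alone; median -0.67, adjusted p = 0.000325, and adjusted p = 0.747 with an estimated correlation), with Cdk1 at -0.67 ± 0.10. Endoplasmic reticulum stress genes were lower in 9 of 16 (9 adjusted over the list alone; median -0.40, adjusted p = 0.000521, and adjusted p = 0.614 with an estimated correlation), with Dnajb9 at -0.73 ± 0.12 and Ddit3 at -0.71 ± 0.15. Xenobiotic genes were lower in 4 of 7 (5 adjusted over the list alone; median -0.65, adjusted p = 0.00129) and hepatocyte identity genes in 4 of 18 (5 adjusted over the list alone; median -0.27, adjusted p = 0.00393). Cytosolic ribosomal protein genes were higher in 7 of 21 (7 adjusted over the list alone; median 0.22, adjusted p = 0.00126). With an estimated correlation these 3 lists had an adjusted p = 0.0893, 0.56 and 0.747. Ppargc1a stood at -0.58 ± 0.09 (adjusted p = 0.00217). Kupffer and endothelial markers stood at 0.00 and 0.06 here (adjusted p = 0.99 and 0.754).

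This comparison called 2609 genes, 1291 higher and 1318 lower under KAT2B depletion. It called 5788 with the batch term (2968 higher, 2820 lower, all 2609 included) and 5194 within the second batch. The count was 1443 without shWDR5 PBS A, 1519 without shKAT2B PBS A and 1686 with only the libraries of the 2 arms.

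Within single arms glucagon raised Nr4a1 by 3.61 ± 0.10 in shNS (2 against 2 libraries, adjusted p = 3.67e-05), by 3.46 ± 0.12 in shWDR5 (2 against 1, adjusted p = 2e-04) and by 2.60 ± 0.12 in shKAT2B (2 against 1, adjusted p = 0.00144). Sik1 rose by 2.22 ± 0.09, 1.80 ± 0.10 and 1.81 ± 0.10, and Slc7a2 by 2.10 ± 0.08, 1.40 ± 0.10 and 1.51 ± 0.10. Ppargc1a rose by 1.84 ± 0.10, 1.51 ± 0.13 and 1.67 ± 0.13, and Egln3 by 2.51 ± 0.13, 1.66 ± 0.16 and 1.96 ± 0.16. In shNS, Tat rose by 3.24 ± 0.32 (adjusted p = 0.0128), and G6pc at 3.71 ± 0.51 and Pck1 at 2.10 ± 0.46 did not pass (adjusted p = 0.0662 and 0.407). The call of Tat ended without shNS PBS B, shNS glucagon A or shNS glucagon B (adjusted p = 0.0697, 0.0511 and 0.0969). G6pc passed without shWDR5 glucagon A or B (0.0332 and 0.0334), as did Pck1 (0.0455 and 0.0451). G6pc was at 2.73 ± 0.62 in shWDR5 and 2.76 ± 0.62 in shKAT2B, Pck1 at 1.36 ± 0.56 and 1.22 ± 0.56, and Tat at 2.32 ± 0.39 and 3.06 ± 0.39, and none of these passed (adjusted p from 0.109 to 1). All 3 genes passed in every arm with the batch term. Of the 22 CREB and cAMP immediate targets, 7 rose in shNS, 5 in shWDR5 and 5 in shKAT2B (14, 10 and 10 adjusted over the list alone), with medians of 0.76, 0.72 and 0.50. The list passed in each arm at the preset correlation (adjusted p = 2.13e-38, 4.31e-26 and 2.06e-12), and in shKAT2B it had an adjusted p = 0.117 with an estimated correlation. In shNS the gluconeogenesis list (median 0.13, 3 of 14 higher, 5 adjusted over the list alone) and the amino acid list (median 0.21, 2 of 11 higher, 3 adjusted over the list alone) also passed with an estimated correlation (adjusted p = 0.0281 and 0.0169), as the CREB list did in shNS and shWDR5 (0.0143 and 0.0305). The hepatocyte identity list passed in shNS with a median of only 0.06 and 1 of 18 members higher (3 adjusted over the list alone; adjusted p = 2.82e-07, and adjusted p = 0.0492 with an estimated correlation). Its median was 0.15 in the first batch and 0.03 in the second, and at the preset correlation the call ended without shNS PBS A (adjusted p = 0.0503). With the batch term the adjusted p with an estimated correlation was 0.102 for the first 2 of these lists and 0.304 for hepatocyte identity. Other lists passed camera at the preset correlation in the depleted arms, among them Kupffer markers in both and endothelial markers in shKAT2B. These marker calls each ended without 1 library. Within the second batch the Kupffer medians were 0.07 in shWDR5 and 0.11 in shKAT2B, and the endothelial median in shKAT2B was 0.09.

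Called genes numbered 22 in shNS, 10 in shWDR5 and 7 in shKAT2B, all higher, against 222 (142 higher, 80 lower), 87 (56 and 31) and 74 (57 and 17) with the batch term. That limma called 0 genes lower goes with 250, 162 and 182 genes of either direction at an unadjusted p under 0.05. Chance alone would give 574, so these p-values are not calibrated and the 0 does not show that no gene fell. In shNS the count was 13 without shNS PBS A, 10 without shNS PBS B and 9 without either shNS glucagon library. In shWDR5 it was 1 without either shWDR5 glucagon library, Nr4a1 being the gene called without any 1 of the 9 libraries that could be left out, and 5 without any 1 of the shNS libraries or of the shKAT2B glucagon libraries. In shKAT2B it was 3 without either shNS glucagon or either shKAT2B glucagon library and 4 without either shWDR5 glucagon library, and Nr4a1, Sik1 and Slc7a2 passed without any 1 of the 9 that could be left out. The lone PBS library of each of these arms could not be left out, since the arm's glucagon effect and its interaction rest on it. In median-centred libraries Egln3 missed in shWDR5 and in shKAT2B (adjusted p = 0.104 and 0.0623). A smaller count in 1 arm does not show a smaller response, which the interaction tests address.

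In glucagon-treated cells KAT2B depletion lowered Nr4a1 (-0.82 ± 0.10, adjusted p = 0.0212), Tdo2 (-1.45 ± 0.12), the ubiquitin ligase gene Rnf125 (-1.44 ± 0.09) and Ttr (-0.98 ± 0.12), and raised Alox5 by 2.10 ± 0.22 and Cd80 by 1.89 ± 0.25 (2 against 2 libraries). Nr4a1 differed by -0.79 in the first batch and by -0.86 in the second, and its call ended without either shNS library of either treatment or either shKAT2B glucagon library (adjusted p of up to 0.215). WDR5 depletion under glucagon lowered Wdr5 (-1.66 ± 0.10), Vkorc1 (-1.28 ± 0.12), Hdgf (-1.11 ± 0.09), the palmitoyltransferase gene Zdhhc9 (-0.85 ± 0.09) and Arf3 (-0.77 ± 0.08), and raised the protease inhibitor gene Serpinb8 by 1.17 ± 0.11. Among hepatocyte identity genes, 2 of 18 fell and 0 rose under KAT2B depletion (9 and 0 adjusted over the list alone; median -0.46, adjusted p = 1.15e-09, and adjusted p = 0.0536 with an estimated correlation). CREB and cAMP immediate targets had 1 of 22 members lower, Nr4a1, and 1 higher, Btg2, which is also in the p53 list (5 and 1 adjusted over the list alone; median -0.28, adjusted p = 0.00546, and adjusted p = 0.355 with an estimated correlation). The call of Btg2 (0.58) ended without any 1 of 8 libraries (adjusted p of up to 0.271), after quantile normalization (0.0554), in median-centred libraries (0.069), without the filter on low values (0.0538) and without a trend (0.0528). A stricter filter on low values ended this list's call (-0.21, adjusted p = 0.0652).

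There were 154 called genes for KAT2B depletion under glucagon (51 higher, 103 lower) and 6 for WDR5 depletion (1 higher, 5 lower), against 3127 and 2716 with the batch term. For KAT2B the count was 0 without either shNS glucagon library, so that no single gene named under glucagon kept its call there, 46 without either shNS PBS library, 41 without either shWDR5 glucagon library, 87 without shKAT2B glucagon A and 1 without shKAT2B glucagon B. For WDR5 it was 0 without either shNS glucagon or either shWDR5 glucagon library, and 1 without either shNS PBS or either shKAT2B glucagon library. The counts of 0 are those of limma with 1770 genes (KAT2B) and 1505 genes (WDR5) at an unadjusted p under 0.05 over all 10 libraries, and with only the 4 libraries compared both counts were 0 as well.

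The interactions ask whether a depletion changed the response to glucagon. Of the 26 genes induced at least to a log2 fold change of 1, a set that includes Nr4a1, G6pc, Tat, Pck1, Ppargc1a, Sik1 and the insulin signalling gene Irs2, 22 had a smaller glucagon effect in shWDR5 and 23 in shKAT2B than in shNS. Their median glucagon effect was 1.75 in shNS, 1.46 in shWDR5 and 1.49 in shKAT2B. Both comparisons subtract the glucagon effect of the same shNS libraries, so they are not independent. The median interaction was -0.38 for WDR5 (limma's fry, adjusted p = 0.0284 over the 4 set tests) and -0.48 for KAT2B (adjusted p = 0.0262). With the batch term the medians were -0.41 and -0.47 (adjusted p = 0.0656 for both), so that neither passed after adjustment over the 4 tests. Within the second batch, with 1 library per group, the set's median effect was 1.89 in shNS, 1.50 in shWDR5 and 1.46 in shKAT2B. Both calls depended on single libraries, with adjustment over the set tests in each case. The WDR5 call ended without either glucagon library of any of the 3 arms (6 libraries, medians from -0.44 to -0.32, adjusted p from 0.0554 to 0.102). The KAT2B call ended without either glucagon library of shNS or shKAT2B or without shWDR5 glucagon B (5 libraries, medians from -0.48 to -0.43, adjusted p from 0.0548 to 0.102). With all 78 genes called higher, and no minimum fold, the median was -0.14 for each depletion and neither passed (adjusted p = 0.16). After quantile normalization and in median-centred libraries the KAT2B call held (adjusted p = 0.0404 and 0.0286) and the WDR5 call did not (0.0596 and 0.0526). In glucagon-treated cells the set stood at -0.17 for WDR5 against shNS (20 of 26 lower) and at -0.45 for KAT2B (22 of 26 lower), and in PBS, within the second batch, at 0.28 and 0.19.

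**Figure D5:**
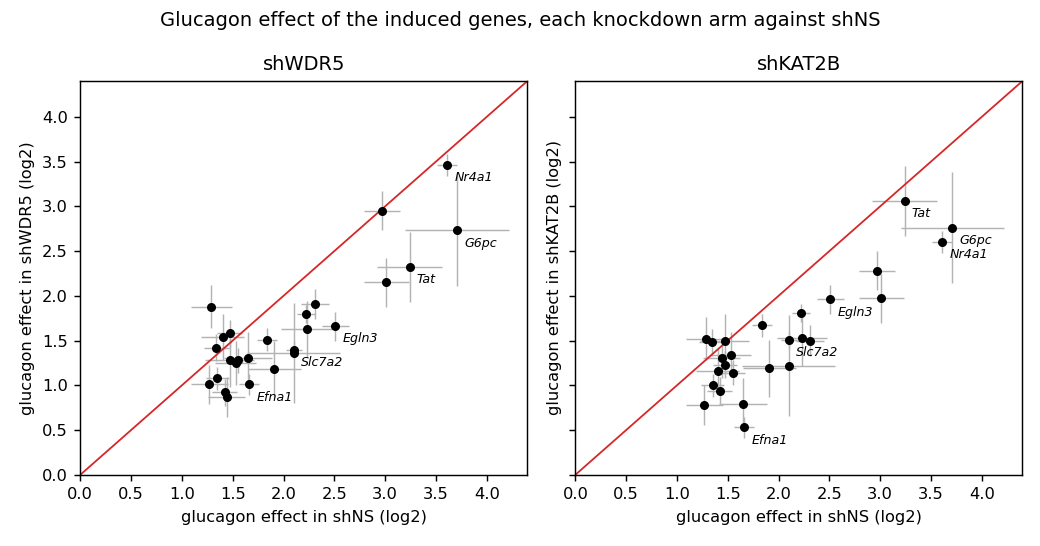
Glucagon effect of the 26 induced genes in shWDR5 (left) and shKAT2B (right) against that in shNS (both axes log2; grey bars for the standard error; red line for equal effects). Below the line lie 22 genes in shWDR5 and 23 in shKAT2B.

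Single genes did not pass in either interaction: limma called 0 genes for WDR5 and 0 for KAT2B, with 20 and 36 at an unadjusted p under 0.05 where 574 would be expected by chance. Counts so far below 574 show that these p-values are not calibrated, so 0 calls do not show that no gene interacts. The batch difference stays in the residuals of this fit, and the median standard error was 0.22, against 0.13 with the batch term. With the batch term 0 and 2 were called (255 and 279 at an unadjusted p under 0.05). The 2 were the ephrin gene Efna1 at -1.16 (adjusted p = 0.00773) and Nr4a1 at -1.04 (adjusted p = 0.015), both with a smaller glucagon effect under KAT2B depletion, and without the batch term they stood at -1.13 ± 0.15 and -1.01 ± 0.16. For WDR5 the interactions of Slc7a2 (-0.70 ± 0.12), Efna1 (-0.64 ± 0.15) and Egln3 (-0.85 ± 0.21) did not pass. The 3 genes that glucagon lowered by at least 1 on the log2 scale, Ccn1, Edn1 and F3, had median interactions of 0.36 for WDR5 and 0.59 for KAT2B (limma's fry, adjusted p = 0.393 and 0.329).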

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

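The fits with the library batch and the tests of explanations for the smaller glucagon induction were chosen after the result was seen; the set tests without the batch, the set with no minimum fold and the leaving out of libraries were set before.

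Of the 26 genes that glucagon induced, 22 had a smaller glucagon effect under WDR5 depletion and 23 under KAT2B depletion, which is a difference between groups: the median interaction was -0.38 for WDR5 and -0.48 for KAT2B. An unequal spread of the library batches over the groups was argued against as the whole cause, since with the batch as a term the medians were -0.41 and -0.47, although the adjusted p of both rose from 0.0284 and 0.0262 to 0.0656 (limma's fry) in a fit with 3 residual degrees of freedom in place of 4, so that neither call was kept. Leaving out 1 library also ended the WDR5 call in 6 cases and the KAT2B call in 5, up to an adjusted p of 0.102 for both, with medians from -0.44 to -0.32 and from -0.48 to -0.43 in those cases, and the lone PBS library of the arm could not be left out. With no minimum fold for the set (78 genes) both medians were -0.14 and neither passed (adjusted p = 0.16). Both interactions share the shNS libraries, so a departure of these would move both the same way. That was not excluded, and both calls ended without either shNS glucagon library. The comparisons of glucagon libraries that follow use the shNS glucagon libraries too. A high value of the lone PBS library of each depletion arm would leave the glucagon libraries equal to those of shNS. For KAT2B they were lower, with a median of -0.45 that passed fry, without adjustment, in the fit with the batch. That argues against a high PBS library as the only cause. A drop in both treatments together with a high PBS library would give the same value. With 1 PBS library in the arm this was not excluded. For WDR5 the median was -0.17, which did not pass. A weaker induction and a high PBS library therefore cannot be told apart for WDR5 with 1 PBS library. A weaker transcriptional response to glucagon after KAT2B depletion is a candidate explanation that stays a hypothesis, since it was found and tested on the same libraries.

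Of the 28 gene lists, 8 passed camera at the preset correlation for the interaction of glucagon with WDR5 depletion and 9 for that with KAT2B depletion, a difference between groups. None of these 17 passed with an estimated correlation, where the smallest adjusted p was 0.2 for WDR5 and 0.193 for KAT2B, and limma called 0 of their members. Leaving out 1 library ended 5 of the 8 calls and 8 of the 9. Those that held in each of the 9 such fits that could be run, and with the batch term, had small medians; the lone PBS library of the depleted arm, on which each interaction rests, could not be left out. For WDR5 they were gluconeogenesis (-0.23 over 14 members, adjusted p = 4.58e-06), amino acid catabolism and the urea cycle (-0.07 over 11, adjusted p = 0.000427) and hepatocyte identity (-0.18 over 18, adjusted p = 2.07e-06). For KAT2B it was CREB and cAMP immediate targets (-0.24 over 22, adjusted p = 9.99e-10). These lists are not separate results. Tat is in both the amino acid and hepatocyte identity lists, and Ppargc1a and Sik1 are in both the gluconeogenesis and CREB lists. All of these genes, with G6pc, Pck1 and Slc7a2, are also in the induced set. Adjusted over the list alone, 1 member was lower in each amino acid list and 1 in the CREB list for KAT2B, and 0 in the other lists. The other calls each ended without 1 of up to 3 libraries, and the adjusted p given is the highest so reached. For WDR5 they were CREB and cAMP immediate targets (-0.08 over 22, 0.165), the interferon response (0.38 over 16, 0.0865, with 1 such library), cytosolic ribosomal proteins (-0.09 over 21, 0.376), Kupffer cell and leukocyte markers (-0.29 over 15, 0.868) and endothelial markers (-0.24 over 14, 0.894). In median-centred libraries both marker lists ended too (adjusted p = 0.123 and 0.195), the endothelial list also after quantile normalization (0.06), and without the filter on low values the CREB and endothelial lists (0.161 and 0.111). For KAT2B they were gluconeogenesis (-0.15 over 14, 0.176), amino acid catabolism and the urea cycle (-0.09 over 11, 0.282), cholesterol synthesis (-0.21 over 15, 0.966), the cell cycle (-0.34 over 19, 0.904), cytosolic ribosomal proteins (-0.06 over 21, 0.966), TGF-beta and extracellular matrix (0.14 over 13, 0.603), Kupffer markers (-0.46 over 15, 0.84) and endothelial markers (-0.35 over 14, 0.855). The endothelial list ended in median-centred libraries as well (0.0699). A stricter filter on low values ended the TGF-beta list (0.185) and the endothelial list for both depletions (0.0958 for KAT2B and 0.265 for WDR5). For KAT2B all 8 ended with the batch term, where their medians lay between -0.10 and 0.03. With the batch term the WDR5 medians were 0.11 for the interferon response, which passed, and 0.09 and 0.03 for the Kupffer and endothelial markers, which did not.

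Features with no single gene name, which the comparisons of genes did not use, also held a signal: 6 of 6328 tested were called higher under glucagon over the 3 arms (limma, Benjamini-Hochberg over these features) and 16 with the batch term. The 6 stood between 0.52 ± 0.07 (feature 10552311) and 1.32 ± 0.18 (feature 10365545) on the log2 scale, with adjusted p of 0.0316 and 0.0444.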

How the results depend on the processing

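Fits with the library batch as a term, on the second batch alone and without a pseudocount were chosen after the results were seen. With the batch term 385 genes were called for the shared glucagon effect, 4227 for WDR5, 4768 for KAT2B and 5788 for KAT2B against WDR5. It gave 222, 87 and 74 for glucagon in shNS, shWDR5 and shKAT2B, 2716 and 3127 for WDR5 and KAT2B under glucagon and 2 for the KAT2B interaction. Within the second batch the first 4 counts were 309, 3202, 4263 and 5194. With the replicate letter as a block they were 290, 3065, 3397 and 4139. The glucagon counts per arm were then 222, 1701 and 3014, those under glucagon 2716 and 3127, and the interactions 545 and 1383. The letter sets the lone PBS libraries with the A libraries although their values lay with the B libraries, so its per-arm and interaction counts in the depleted arms carry the batch difference. With only the libraries of the 2 arms compared, 813 genes were called for WDR5 and 1686 for KAT2B against WDR5, and with only the 4 libraries compared 0 for either depletion under glucagon. WDR5 under glucagon gave 17 genes after quantile normalization, 16 in median-centred libraries and 2 without a trend. The cause was not tested.

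Without a minimum fold the induced set had a median of -0.14 under each depletion and neither passed (adjusted p = 0.16 over the 4 set tests). With the replicate letter as a block both calls ended as well (-0.32 and -0.43, adjusted p = 0.0844). The WDR5 call also ended after quantile normalization (adjusted p = 0.0596) and in median-centred libraries (0.0526). For the 3 repressed genes camera with its preset correlation passed at 0.36 and 0.59, where fry and camera with an estimated correlation did not (adjusted p = 0.154 and 0.145 for the latter). Of the 85 list tests that passed, 9 passed with an estimated correlation. Kupffer markers turned from lower to higher under glucagon, to 0.10 over the arms within the second batch and to 0.15 in shWDR5 with the batch term. Leaving out 1 library at a time gave 50 to 101 genes for the shared glucagon effect, 300 to 1414 for WDR5, 598 to 2122 for KAT2B and 1443 to 2680 for KAT2B against WDR5. It gave 9 to 22, 1 to 11 and 3 to 7 for glucagon in shNS, shWDR5 and shKAT2B, 0 to 6 and 0 to 156 for WDR5 and KAT2B under glucagon and 0 for both interactions. The induced set ranged from -0.44 to -0.30 for WDR5 and from -0.52 to -0.41 for KAT2B, with the call ended by 6 and by 5 of the libraries, up to an adjusted p of 0.102, the repressed set from 0.12 to 0.61 and from 0.43 to 0.78, and 71 to 105 list tests passed. Kat2b and Wdr5 kept their calls over both treatments in all fits run. On an array, genes near background are compressed, so folds from low signals are limited by the background.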

Other observations

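The tests of the cell cycle list and the fits with the library batch in this part were chosen after the result was seen, and the tests of what separates the library batches and of other splits of the libraries before.

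The 2 library batches differed in 6467 genes, 2011 higher and 4456 lower in the second batch (limma, Benjamini-Hochberg). In fits with the same term the depletions and glucagon called up to 5788. Genes far apart, picked after their values were seen, include Saa3, a serum amyloid of the acute phase, higher in the second batch by 2.68 ± 0.18, Fcer1g and Adgre1, higher by 1.30 and 1.27, and Tgfb3, lower at -1.34. All 15 measured cholesterol synthesis genes were higher, and 14 of 16 interferon response genes were lower (median -0.47), among them Ifit1 at -1.07, though neither list passed with an estimated correlation (adjusted p = 0.206 and 0.356). These libraries were sorted by the same values, so the counts describe the split and do not test it.

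A different overall scaling of the arrays was argued against as the source of this split, since the leading component held 77 percent of the residual variance after quantile normalization, against 78 percent before. A lower share of hepatocytes would raise the markers of all other liver cells alike, and the markers moved apart, with Kupffer markers at 0.52, endothelial markers at 0.51 and stellate markers at -0.37. A different mix of other cells and cultures made on separate days are candidate explanations among others, which the labels do not allow to be tested. Quantile normalization acts on all genes of a library at once. It therefore does not exclude that handling of the RNA or arrays changed some genes and not others.

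Cell cycle genes were higher under WDR5 depletion. An unequal spread of the batches was argued against, with a median of 0.55 once the batch was a term. A higher share of non-parenchymal cells was not excluded. KAT2B depletion had higher Kupffer and endothelial markers (0.30 and 0.27 with the batch term, against 0.17 and 0.19 for WDR5). Its cell cycle median was -0.13, but KAT2B depletion may itself change these genes, so that arm cannot decide the question for WDR5. Between the library batches the cell cycle, Kupffer and endothelial lists rose together, at 0.61, 0.52 and 0.51. Higher expression of cell cycle genes may follow from WDR5 depletion, as a hypothesis found and tested on the same libraries. With an estimated correlation the list did not pass in either fit (adjusted p = 0.873, and 0.525 with the batch term).

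Of 15 cholesterol synthesis genes 11 were lower under KAT2B depletion in the fit with the batch (12 adjusted over the list alone; median -0.30, camera adjusted p = 6.89e-06, and adjusted p = 0.494 with an estimated correlation). Without the batch term 0 were called and the list did not pass (-0.23, adjusted p = 0.115).

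Other splits of the libraries into groups of the same sizes were fitted in the same way as the real split. For each depletion these fits, real split included, used only the libraries of the 2 arms compared, so the real counts given here differ from those over all 10 libraries (1246 and 4227 for WDR5, 1792 and 4768 for KAT2B, without and with the batch term). For the shared glucagon effect 2 of 54 splits called at least as many genes as the real 106, few enough to pass the rule set before. The highest other called 6392. That split follows the library batch and points to a structure of the samples. With the batch term 1 of 53 splits, the real one, reached 385, and the highest other called 224. For WDR5 without the batch term chance was not excluded: 2 of 34 splits reached the real 813, and the highest other, which follows the batch, called 2195. With the batch term 1 of 33, the real one, reached 4648, and the highest other called 889. For KAT2B without the batch term chance was not excluded either, with 2 of 34 at or above 1331 and the batch split at 1748. With the term 1 of 33, the real one, reached 4765, against 2169 for the highest other. In the fits without the term only the batch split exceeded the real one, for glucagon and for both depletions. The next split called 2 genes for glucagon, 2 for WDR5 and 0 for KAT2B. These verdicts therefore differ only through the number of splits, and chance is not excluded more firmly for glucagon than for the depletions. The batch was read from residuals of a fit with the real arms and treatments, and every split used that same batch. Fits with the term can therefore favour the real split, so they cannot exclude chance for glucagon or for either depletion. For KAT2B against WDR5 the 10 splits are too few, with 1686 real and 0 for the highest other (limma), and 4863 against 0 with the batch term.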
